A study of Mus musculus with 26 samples.

How the data were processed

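The material was 26 Affymetrix expression arrays of immortalized mouse embryonic fibroblasts (MEFs), fibroblasts grown from mouse embryos and passed into permanent culture. Per the labels, 3 parental lines named WA, WB and WC were each infected with 3 retroviral vectors: the empty pBabe-puro vector, the same vector carrying human c-myc, and the same vector carrying v-src, the tyrosine kinase oncogene of Rous sarcoma virus. Cells were lysed in the dish, total RNA was extracted on columns and biotinylated cRNA was hybridized, per the labels' protocols. Each of the 9 combinations of line and vector had 3 arrays, except v-src in WB with 2, whose replicate 1 was not analysed here. Groups and replicate numbers were read from the titles and characteristics. The free-text description of the samples speaks of another kind of material and was not used.

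The values are linear probe set signals: the authors deposited an intensity for each of 45101 probe sets on every array, computed with MAS5 per the submitters' processing notes, with the version, the probe masking and the detection calls not given in the sources used here. The mean of each array after trimming 2% of probe sets at each end was 500 on all 26 arrays, which is the scaling the deposited intensity values carry. All intensities were above 0. Signals near 0 are dominated by background, and because no detection calls were used, a low signal is a level and not a call of absence. The number of arrays limits the precision. Array medians lay between 89.0 and 134.6.

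Probe sets were named from the platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and were not named, and 9211 were not listed and stayed unnamed. The 64 control probe sets were left out of all tests. Gene IDs of 34754 of the single-gene probe sets were found in the RefSeq gene table of mouse assembly GRCm38.p6, used for names alone, and 0 symbols changed through it. Probe sets whose mean log2 value over all arrays was not above the 40th percentile were left out, and for each gene the remaining probe set with the highest mean was kept. This left 13018 genes for testing of 18193 with a probe set. The value of a named gene is that of the probe set kept, and other probe sets of the same gene can differ from it, also in direction. All per-sample columns were mapped to labelled samples, so 0 were left over.

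From the deposited intensity, log2(value + 23) was computed, with the pseudocount at the 20th percentile of all values rounded to a whole number. Fold changes are on this log2 scale and understate the change of genes with low signal. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend, Benjamini-Hochberg adjustment over the 13018 genes and a threshold of 0.05 on the adjusted p. For comparisons over the lines, arrays of the same line and vector were averaged first, so that n = 3 lines. The 9 averages were fitted with parental line and vector as terms (4 residual and 3.9 prior degrees of freedom). An SE over the lines rests on a residual variance pooled over the 3 vectors and adjusted by limma towards that of other genes. A gene therefore has the same SE in all comparisons over the lines. This SE is not the spread between lines of the named effect alone, which can differ from it. For comparisons within a line, between lines and for the difference of effects between lines, the 26 arrays were fitted with 9 means (17 residual and 6.2 prior degrees of freedom). Nothing in the labels says that replicates came from separate cultures or infections, so p-values within a line measure the spread between arrays, which may be technical.

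The 27 gene lists were tested with camera at a preset correlation of 0.01 on the 9 averages, adjusted over the 81 tests of 27 lists and 3 comparisons. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. The lists covered ribosome biogenesis and nucleolus, cytosolic ribosomal proteins, nucleotide, folate and polyamine synthesis, DNA replication and G1/S, G2/M and mitosis, glycolysis and lactate export, oxidative phosphorylation, mitochondrial ribosome, import and chaperones, collagens and extracellular matrix, contractile and serum response factor targets, integrins and adhesion receptors, extracellular proteases and their inhibitors, cytokines and STAT3 response, ERK pathway output and AP-1, interferon response, p53 targets, cholesterol synthesis, integrated stress response and unfolded protein response, Hox genes, sex chromosome genes, and markers of fibroblasts, macrophages and blood, endothelium, epithelium, skeletal muscle, neural and glial cells, and adipocytes and chondrocytes. Member counts are given over all genes tested and adjusted over the list alone.

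The design, the lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule named, for each vector against empty vector, the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in all 3 lines, and the 5 largest each way for v-src against c-myc. It also named up to 4 members of each list past the threshold with the largest change, the 3 largest differences each way for each pair of lines, the 5 smallest p for each difference of effects between lines, and in every case Myc, Mycn, Mycl, Src, Fyn, Yes1, Cdkn2a, Cdkn1a, Mdm2, Trp53 and the sex chromosome genes. Trp53 has no probe set under its name in the annotation used and is not analysed here. Examples of the overlap, genes of the hypoxia list and the macrophage and blood markers named beside Cd53 and Cd14 were chosen after their values were seen. Genes known only by clone or predicted names were passed over.

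The scripts were tested on simulated data in which known genes changed. In the c-myc comparison over the lines, limma recovered 6.0% of 67 genes changed by 0.5 on the log2 scale, 58.2% of 67 changed by 1 and 93.9% of 66 changed by 2, with 5 calls among unchanged genes. The simulated v-src comparison held no change and gave 0 calls. In the comparison within WA, 85.8% of 351 genes with a simulated difference of at least 1 either way were recovered. That difference held the planted change and the simulated spread between groups. For the c-myc effect differing between lines, 20.9% of 67, 52.2% of 67 and 89.4% of 66 genes were recovered at 0.5, 1 and 2, with 4 calls among unchanged genes. Few of the 13018 genes were given a change, while 2576 were called with c-myc over the lines in the data. The adjusted p depends on that share, so the recovered shares need not hold for the data.

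Alternatives were pseudocounts of 5.75 and 92, quantile normalization, no filter and a filter at the 60th percentile, no intensity trend, the mean of a gene's probe sets, all 26 arrays as separate values, line and vector as a random block (estimated correlation 0.292), the replicate number as a block, leaving out each line and each array in turn, and camera with an estimated correlation. A pair of alternatives was chosen after seeing the data. The first was camera run on all 26 arrays with a correlation estimated there, because the 9 averages leave 4 degrees of freedom. The second left out together the 2 arrays that deviated most from their group. The correlation and covariance of the c-myc and v-src responses across genes were set against 50 simulations of unchanged groups that share the empty-vector arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The breast cancer signature that the study's design refers to was not analysed here.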

Results

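Immortalized mouse embryonic fibroblasts of 3 parental lines, WA, WB and WC, carrying an empty retroviral vector, human c-myc or v-src were compared on 26 arrays. Of the variance among the 9 averages of line and vector, 41.9% went with the parental line, 42.4% with the vector and 15.8% with their combination. Arrays of the same line and vector correlated across genes with r between 0.960 and 0.983, and arrays of different groups with r between 0.863 and 0.959. Genes are not independent replicates in these values of r.

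**Figure D1:**
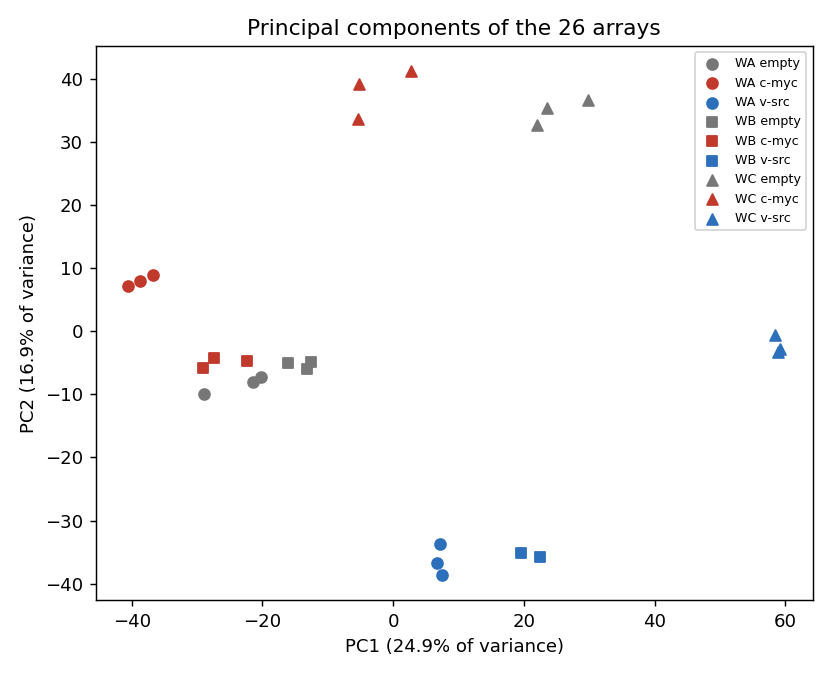
First 2 principal components of the 26 arrays, which hold 24.9% and 16.9% of the variance of 13018 genes. Each point is 1 array.

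Smoc2, which codes for a matricellular protein, fell with c-myc by 3.15 on the log2 scale (SE 0.61, adjusted p = 0.0126, n = 3 lines), 8.85-fold. Ccn5, a secreted growth regulator of fibroblasts and smooth muscle, changed by -2.89 (SE 0.25, adjusted p = 0.00202), and Pdgfra, the receptor for platelet-derived growth factor, by -2.72 (SE 0.39, adjusted p = 0.00538). Papss2, which makes the sulfate donor for proteoglycans, changed by -2.68 (SE 0.24), Cemip by -2.70 (SE 0.46), Dkk2 by -2.65 (SE 0.39) and Slc1a6 by -2.67 (SE 0.48). Dcn, the proteoglycan decorin, changed by -2.80 (SE 0.77, adjusted p = 0.0395, -1.86 in WA, -4.32 in WB and -2.21 in WC). Its call was lost with no filter, with the higher pseudocount and without an intensity trend.

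The largest rises with c-myc were those of Them6 (2.09, SE 0.37), Ydjc (2.08, SE 0.16, adjusted p = 0.00202, 1.80 in WA, 2.32 in WB and 2.12 in WC), Epop (2.06, SE 0.29) and the kinase gene Dyrk3 (2.03, SE 0.25, adjusted p = 0.00420). Smpdl3b rose by 1.79 (SE 0.27), Spire2 by 1.79 (SE 0.33), Reep6 by 1.67 (SE 0.39), Dusp9 by 1.62 (SE 0.27) and Rbm38 by 1.47 (SE 0.14). E2f5 rose by 1.85 (SE 0.20) on 1 probe set, while its 2 other probe sets changed by -0.10 and -0.10. The cells' own Myc fell by 2.66 (SE 0.43, adjusted p = 0.00752, -3.87 in WA, -1.46 in WB and -2.66 in WC). Its signal went from 3191 ± 364 (SD, n = 3 arrays) to 201 ± 58.8 in WA, from 3087 ± 221 to 1120 ± 199 in WB and from 1817 ± 249 to 266 ± 21.3 in WC. This is a single mouse probe set, which need not detect the human c-myc of the vector. Mycn fell by 0.24 with c-myc (SE 0.06, adjusted p = 0.0267) and by 0.27 with v-src (SE 0.06, adjusted p = 0.0236) on a probe set with a group mean of 13710 or more, while the means of its 2 other probe sets were at most 81.5. The c-myc call was lost without WA empty replicate 3 (-0.18, adjusted p = 0.0597) and without WC empty replicate 1 (-0.20, adjusted p = 0.0753). The v-src call was lost without WC empty replicate 1 (-0.22, adjusted p = 0.0615), without WC v-src replicate 1 (-0.24, adjusted p = 0.0590) and after quantile normalization. Both Mycn calls were also lost with no filter, without an intensity trend and without each line, where adjusted p reached 0.162. Fyn, a Src family kinase, fell by 0.74 (SE 0.16, adjusted p = 0.0198), and Mycl (-0.07, and 0.07 and -0.49 on its 2 other probe sets), Yes1 (0.16), Src (-0.09), Cdkn2a (-0.34), Cdkn1a (-0.22) and Mdm2 (0.35) were not called over the lines. By the limma F test the c-myc effect differed between lines for Fyn (adjusted p = 0.0173) and Mdm2 (0.00307).

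Among ribosome biogenesis genes, 29 of 33 rose with c-myc (33 adjusted over the list alone), with a median of 0.71 (0.62 in WA, 0.50 in WB and 0.95 in WC, camera adjusted p = 7.88e-17, adjusted p = 0.364 with an estimated correlation). Nolc1, a nucleolar chaperone, rose by 1.08 (SE 0.11), Polr1b, a subunit of RNA polymerase I, by 1.05 (SE 0.10) and Nop16 by 1.00 (SE 0.15). Of 32 genes of the mitochondrial ribosome, import and chaperones, 23 rose (30 adjusted over the list alone, median 0.50, camera adjusted p = 7.19e-13, adjusted p = 0.364 with an estimated correlation), led by Mrps5 (0.94, SE 0.11). Nucleotide, folate and polyamine synthesis had 16 of 26 members up (18 adjusted over the list alone, median 0.45, camera adjusted p = 9.28e-08, adjusted p = 0.375 with an estimated correlation). Mthfd1 changed by 1.04 (SE 0.14) and Gart by 1.04 (SE 0.11). Oxidative phosphorylation had 13 of 37 up (22 adjusted over the list alone, median 0.22, camera adjusted p = 1.02e-07, adjusted p = 0.375 with an estimated correlation). Cyc1 changed by 0.58 (SE 0.09). Of 26 cytosolic ribosomal proteins, 6 rose (12 adjusted over the list alone, median 0.16, camera adjusted p = 3.54e-06, adjusted p = 0.364 with an estimated correlation), Rpl14 by 0.67 (SE 0.15).

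Genes that start DNA replication also rose with c-myc: 15 of 30 (20 adjusted over the list alone, median 0.41, camera adjusted p = 3.98e-09, adjusted p = 0.364 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 0.96 (SE 0.17), Mcm5, a part of that helicase, by 0.85 (SE 0.10) and Cdt1 by 0.84 (SE 0.08). Mitotic genes had 2 of 29 up (1 adjusted over the list alone, median 0.22, camera adjusted p = 0.00617, adjusted p = 0.740 with an estimated correlation). In glycolysis and lactate export 2 of 17 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0752), and the lactate carrier Slc16a1 rose by 1.34 (SE 0.26). The fall was that of Slc16a3 (-0.64), a call lost without WA empty replicate 3, WB empty replicate 1, WB empty replicate 2, WA c-myc replicate 1, WC c-myc replicate 3 or both arrays apart (adjusted p = 0.0527 to 0.0912). Cholesterol synthesis had 1 of 17 up (0 adjusted over the list alone, 4 at unadjusted p under 0.05 in limma), with a median of 0.31 (camera adjusted p = 0.0223, adjusted p = 0.740 with an estimated correlation, fry adjusted p = 0.331). That gene was Idi1 (0.71), whose call was lost without WC c-myc replicate 1 (0.69, adjusted p = 0.0516) and without both arrays apart (adjusted p = 0.0532).

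Of 34 collagen and matrix genes, 24 fell with c-myc (25 adjusted over the list alone, median -1.03, camera adjusted p = 8.34e-14, adjusted p = 0.0885 with an estimated correlation). Fbln5, needed for elastic fibres, changed by -2.61 (SE 0.28), Lama4, a laminin chain, by -2.68 (SE 0.48) and Thbs2 by -2.05 (SE 0.31). Integrins and adhesion receptors had 13 of 24 down (14 down and 1 up adjusted over the list alone, median -0.63, camera adjusted p = 1.26e-07, adjusted p = 0.199 with an estimated correlation), among them the collagen receptor chain Itga1 (-1.83, SE 0.18) and Cdh11 (-1.33, SE 0.10). Extracellular proteases and inhibitors had 10 of 20 down (10 adjusted over the list alone, median -0.75, camera adjusted p = 5.00e-07, adjusted p = 0.239 with an estimated correlation), with the inhibitors Timp3 (-1.45, SE 0.22) and Timp1 (-1.40, SE 0.30). Contractile genes had 6 of 26 down (7 adjusted over the list alone, median -0.53, camera adjusted p = 6.17e-06, adjusted p = 0.563 with an estimated correlation), with Actg2 (-1.73, SE 0.37) and Tln1 (-0.81, SE 0.09). Tpm2 of this list fell by 0.74, while another of its probe sets changed by 0.19. Fibroblast markers had 4 of 16 down (6 adjusted over the list alone, median -0.46, camera adjusted p = 0.000740, adjusted p = 0.375 with an estimated correlation), among them Thy1 (-1.74, SE 0.35).

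With c-myc, of 28 members of the integrated stress response and unfolded protein response list, 10 fell (14 adjusted over the list alone, median -0.32, camera adjusted p = 1.48e-07, adjusted p = 0.364 with an estimated correlation). The pseudokinase gene Trib3 changed by -2.14 (SE 0.20), Vldlr by -2.10 (SE 0.24) and Chac1 by -1.72 (SE 0.21). Cytokine and STAT3 response genes had 6 of 22 down (6 adjusted over the list alone, median -0.39, camera adjusted p = 0.00180, adjusted p = 0.424 with an estimated correlation). Cebpd changed by -1.75 (SE 0.36) and Osmr, a receptor chain for oncostatin M, by -1.61 (SE 0.20). ERK output genes had 4 of 27 down (2 adjusted over the list alone, camera adjusted p = 0.146), with medians of -0.89 in WA, 0.74 in WB and -0.63 in WC. Interferon response genes had 1 of 19 down (0 adjusted over the list alone, 2 at unadjusted p under 0.05 in limma, median -0.41, camera adjusted p = 0.0844, fry adjusted p = 0.569). The mean log2 signal of this list went from 8.68 with the empty vector to 7.66 with c-myc in WC. In WA it went from 7.40 to 7.36 and in WB from 7.31 to 7.25. Of 24 p53 targets 3 fell (3 adjusted over the list alone, camera adjusted p = 0.247), among them Phlda3 (-0.83), and of 20 Hox genes Hoxa5 rose (0.76, call lost with the mean of probe sets) and Hoxd8 fell (-0.87, 1 and 1 adjusted over the list alone, camera adjusted p = 0.827).

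In limma, c-myc against empty vector called 2576 of 13018 genes, 1306 higher and 1270 lower, with 4473 at unadjusted p under 0.05. At least 2-fold were 77 rises and 324 falls. The count was 466 without WA, 1339 without WB and 414 without WC, and with all arrays as separate values it was 5801. It was 4194 with line and vector as a random block.

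With v-src the largest rise was that of Il33, the gene of an alarmin cytokine. Il33 rose by 7.26 (SE 0.22, adjusted p = 1.41e-05, n = 3 lines, 6.74 in WA, 7.64 in WB and 7.39 in WC), 153-fold. Its signal with the empty vector was 21.2 in WA, 35.6 in WB and 30.2 in WC, and with v-src 4500 ± 851 (SD, n = 3 arrays), 10520 ± 384 (n = 2) and 8809 ± 839 (n = 3). Upp1, a uridine phosphorylase, rose by 5.62 (SE 0.28, adjusted p = 0.000220), the protease inhibitor gene Serpinb2 by 5.37 (SE 0.95, adjusted p = 0.0110) and the collagenase gene Mmp13 by 5.13 (SE 0.63, adjusted p = 0.00307), 34.9-fold. Further rises were Akr1c18 (4.82, SE 0.51), the mast cell protease gene Mcpt8 (4.49, SE 0.41), Mmp10 (3.98, SE 0.55), Angptl4 (3.90, SE 0.45), Stc1 (3.85, SE 0.27) and Cd53 (3.81, SE 0.29).

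Smoc2 fell with v-src by 4.85 (SE 0.61, adjusted p = 0.00345), 28.8-fold. The small proteoglycan Aspn changed by -3.98 (SE 0.29, adjusted p = 0.000793), Gask1b by -3.80, Slc1a6 by -3.55, the cartilage collagen Col2a1 by -3.16, Ogn by -3.01, the smooth muscle gene Lmod1 by -3.00, Atoh8 by -2.98 (SE 0.25), the protease gene Tll1 by -2.97 (SE 0.71, a call lost without an intensity trend) and the neuronal microtubule gene Map2 by -2.91 (SE 0.19). Dcn rose by 3.34 (SE 0.77, adjusted p = 0.0279). Mouse Src (0.30, SE 0.18, adjusted p = 0.313), which may not detect v-src, Myc (0.09, adjusted p = 0.916), Mycl (-0.18, and 0.19 and -0.68 on its 2 other probe sets), Fyn (-0.15), Yes1 (0.17) and Cdkn2a (0.07) were not called over the lines. By the limma F test the v-src effect differed between lines for Src (adjusted p = 0.00415), Fyn (0.00238) and Cdkn2a (0.0417). Cdkn1a, the gene of the cell cycle inhibitor p21, rose by 1.72 (SE 0.41, adjusted p = 0.0311, 2.42 in WA, 2.24 in WB and 0.49 in WC), a call lost without an intensity trend, and Mdm2 rose by 0.86 (SE 0.17).

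**Figure D2:**
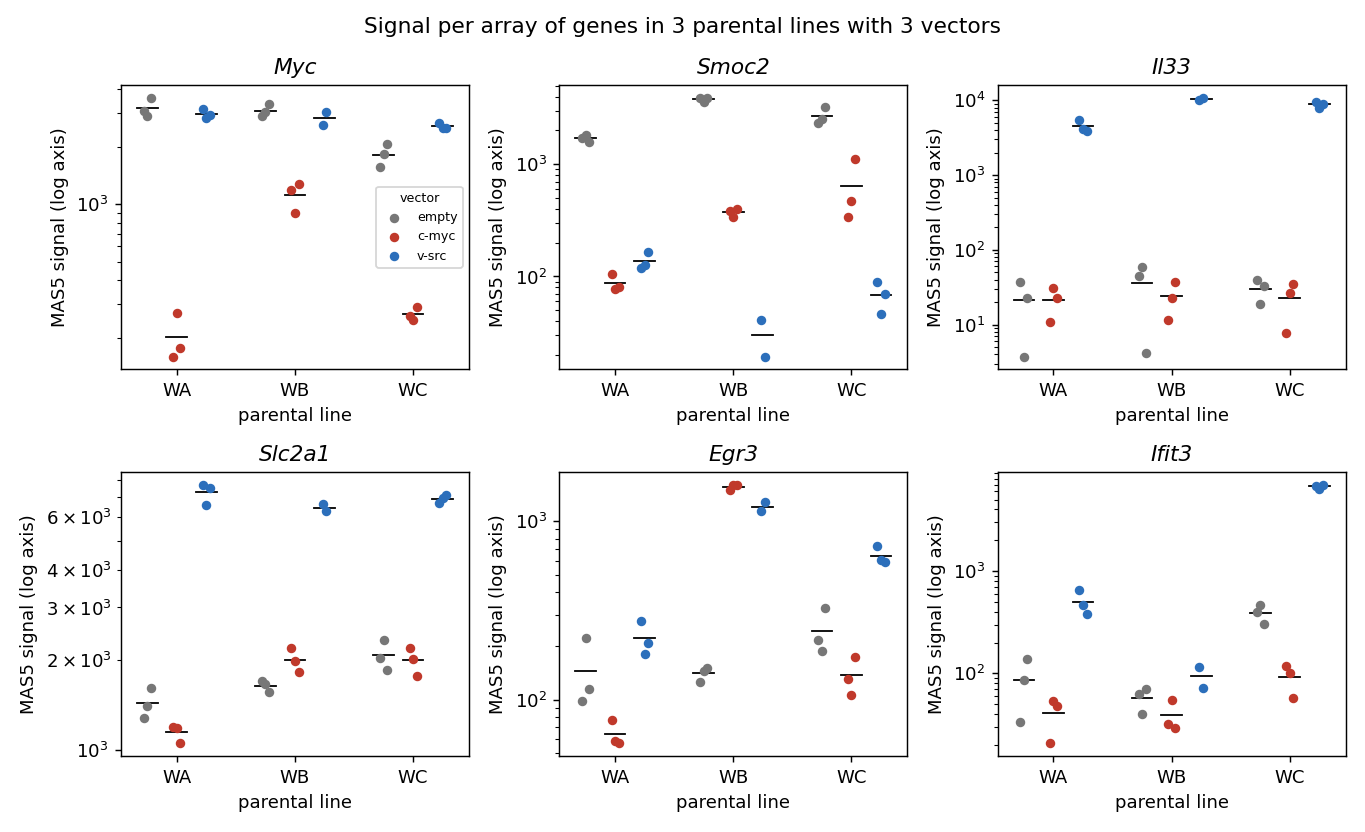
Signal of 6 genes on each array, on a log axis, by line and vector. The black line is the mean of a group.

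Glycolysis rose with v-src: 13 of 17 members (14 adjusted over the list alone), with a median of 1.00 (0.74 in WA, 0.93 in WB and 0.73 in WC, camera adjusted p = 3.98e-09, adjusted p = 0.327 with an estimated correlation). The lactate exporter Slc16a3 rose by 2.97 (SE 0.18), the pyruvate dehydrogenase kinase gene Pdk1 by 2.21 (SE 0.31) and the glucose transporter Slc2a1 by 2.00 (SE 0.18), 4.01-fold. Cytokine and STAT3 response genes had 11 of 22 up (12 adjusted over the list alone, median 0.86, camera adjusted p = 2.04e-06, adjusted p = 0.364 with an estimated correlation). Il6 changed by 3.74 (SE 0.64), Socs3, the feedback inhibitor of this pathway, by 3.26 (SE 0.35) and Bcl3 by 2.97 (SE 0.34). ERK output genes had 4 of 27 up and 1 down (6 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 0.000495, adjusted p = 0.634 with an estimated correlation). Fosl1 changed by 1.73 (SE 0.35) and Spry1 by -1.86 (SE 0.33). Interferon response genes had a median of 1.14 (0.91 in WA, 0.28 in WB and 2.18 in WC, camera adjusted p = 0.000298, adjusted p = 0.623 with an estimated correlation), but 1 of 19 was called up (0 adjusted over the list alone, 7 at unadjusted p under 0.05 in limma, fry adjusted p = 0.246). That gene was Gbp2 (1.61, SE 0.41, adjusted p = 0.0405), whose call was lost after quantile normalization, with no filter, with the higher pseudocount, with the mean of probe sets, without an intensity trend and without the 2 arrays apart from their group.

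Contractile genes fell with v-src, 15 of 26 (21 adjusted over the list alone, median -0.75, camera adjusted p = 1.07e-10, adjusted p = 0.368 with an estimated correlation). Cnn1 changed by -2.40 (SE 0.60, adjusted p = 0.0368) and Actg2 by -1.56 (SE 0.37, adjusted p = 0.0305), and both calls were lost without an intensity trend. Of 34 matrix genes 18 fell and 1 rose (22 and 2 adjusted over the list alone, median -0.56, camera adjusted p = 1.45e-08, adjusted p = 0.127 with an estimated correlation). Postn changed by -2.61 (SE 0.44) and Fbln5 by -2.32 (SE 0.28). Integrins and adhesion receptors had 4 of 24 up and 9 down (6 and 12 adjusted over the list alone, median -0.36, camera adjusted p = 0.0356, adjusted p = 0.364 with an estimated correlation). Itgb7 changed by 2.26 (SE 0.36) and Ncam1 by -2.20 (SE 0.26). The call of this list was lost after quantile normalization. Extracellular proteases and inhibitors went both ways, 6 of 20 up and 3 down (6 and 5 adjusted over the list alone, camera adjusted p = 0.690). The stromelysin gene Mmp3 changed by 3.17 (SE 0.42) and Timp3 by -2.33 (SE 0.22). Fibroblast markers had 1 of 16 up and 4 down (1 and 5 adjusted over the list alone, median -0.22, camera adjusted p = 0.0317, adjusted p = 0.582 with an estimated correlation). Pdpn changed by 2.53 (SE 0.36) and Pdgfrb by -1.87 (SE 0.21). The list call was lost after quantile normalization and with the mean of probe sets.

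With v-src, of 33 ribosome biogenesis genes Nhp2 rose (0.45, a call lost without WC c-myc replicate 1 at adjusted p = 0.0505 and without both arrays apart at 0.0680, 1 adjusted over the list alone, median -0.07, camera adjusted p = 0.496), of 32 mitochondrial ribosome genes 2 rose (1 adjusted over the list alone, camera adjusted p = 0.827) and of 37 oxidative phosphorylation genes 2 fell, Uqcrc1 (-0.40) and Atp5g1 (-0.41, 1 adjusted over the list alone, camera adjusted p = 0.174). The Atp5g1 call was lost without WA empty replicate 3 (-0.39, adjusted p = 0.0561), without WC empty replicate 2 (-0.39, adjusted p = 0.0647) and without both arrays apart (-0.39, adjusted p = 0.0630). In nucleotide synthesis 2 of 26 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.198). Odc1 changed by 0.58 (SE 0.08) and Psph by -1.05, lost without an intensity trend. Of 30 DNA replication genes Rrm1 fell, by 0.65 (SE 0.10, 1 adjusted over the list alone, camera adjusted p = 0.944). Mitotic genes had 3 of 29 down (3 adjusted over the list alone, median -0.25, camera adjusted p = 0.000549, adjusted p = 0.672 with an estimated correlation). Cdc20 changed by -0.48 (SE 0.08). The others were Mki67 (-0.56) and Birc5 (-0.50), and without WC empty replicate 3 both lost their calls (adjusted p = 0.0635 and 0.0585). Birc5 also lost it without WA empty replicate 2 (adjusted p = 0.0504) and Mki67 without WB v-src replicate 2 (adjusted p = 0.0585). Cytosolic ribosomal proteins had 1 of 26 down (0 adjusted over the list alone, 12 at unadjusted p under 0.05 in limma), a median of -0.12 (camera adjusted p = 0.000395, adjusted p = 0.450 with an estimated correlation, fry adjusted p = 0.0186), and turned to 0.03 after quantile normalization. The gene was Rpl4 (-0.21), whose call was lost without WA empty replicate 3, WB empty replicate 2, WC empty replicate 1, WB v-src replicate 3, WC v-src replicate 1 or both arrays apart (adjusted p = 0.0586 to 0.0837).

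Of 28 stress response genes 3 rose and 8 fell with v-src (6 and 9 adjusted over the list alone, median -0.15, camera adjusted p = 0.0426, adjusted p = 0.706 with an estimated correlation). The call of this list was lost after quantile normalization. Slc7a5, a carrier for large neutral amino acids, fell by 1.52 (SE 0.15) and its partner Slc3a2 by 0.78. Of 24 p53 targets 2 rose and 4 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.0875), Phlda3 by 1.09 (SE 0.19) and Ccng1 by 0.68 (SE 0.12). Fdft1 rose by 0.75 as 1 of 17 cholesterol synthesis genes (1 adjusted over the list alone, camera adjusted p = 0.585), and Hoxa5 rose by 1.09 (call lost with the mean of probe sets) as 1 of 20 Hox genes (1 adjusted over the list alone, camera adjusted p = 0.554).

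In limma, v-src against empty vector called 1749 genes, 865 higher and 884 lower, with 3892 at unadjusted p under 0.05. At least 2-fold were 315 rises and 244 falls. The count was 756 without WA, 517 without WB and 562 without WC, 4953 with all arrays as separate values and 3321 with line and vector as a random block.

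Set directly against c-myc, Il33 was higher with v-src by 7.39 (SE 0.22, adjusted p = 1.22e-05, n = 3 lines), Dcn by 6.14 (SE 0.77, adjusted p = 0.00192), Upp1 by 5.96, Serpinb2 by 5.74 and Mmp13 by 5.36. Lower were Aspn (-3.09, SE 0.29), the cadherin gene Cdh3 (-2.93, SE 0.41), Atoh8 (-2.80, SE 0.25), Ogn (-2.49) and Ydjc (-2.43, SE 0.16). Mouse Myc was higher by 2.75 (SE 0.43, adjusted p = 0.00441).

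Ribosome biogenesis had 31 of 33 members lower with v-src than with c-myc (32 adjusted over the list alone, median -0.74, camera adjusted p = 5.40e-16, adjusted p = 0.364 with an estimated correlation), Nop58 by 1.08 (SE 0.13). The mitochondrial ribosome had 25 of 32 lower (28 adjusted over the list alone, median -0.46, camera adjusted p = 1.07e-10, adjusted p = 0.364 with an estimated correlation). Cytosolic ribosomal proteins had 24 of 26 lower (25 adjusted over the list alone, median -0.26, camera adjusted p = 2.36e-10, adjusted p = 0.331 with an estimated correlation). The call of this list was lost after quantile normalization. Nucleotide synthesis had 18 of 26 lower (19 adjusted over the list alone, median -0.50, camera adjusted p = 3.61e-09, adjusted p = 0.364 with an estimated correlation). Mthfd1 differed by -1.26 (SE 0.14) and Cad by -1.17. Oxidative phosphorylation had 23 of 37 lower and 1 higher (29 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 7.78e-09, adjusted p = 0.364 with an estimated correlation). DNA replication had 21 of 30 lower (21 adjusted over the list alone, median -0.51, camera adjusted p = 9.11e-09, adjusted p = 0.364 with an estimated correlation). The repair enzyme gene Ung differed by -1.37 (SE 0.14) and Mcm5 by -1.15 (SE 0.10). Mitosis had 13 of 29 lower (18 adjusted over the list alone, median -0.41, camera adjusted p = 4.33e-07, adjusted p = 0.563 with an estimated correlation). Cdc20 differed by -0.81 (SE 0.08) and Plk1 by -0.73.

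Cytokine and STAT3 response genes had 13 of 22 members higher with v-src than with c-myc (15 adjusted over the list alone, median 1.33, camera adjusted p = 1.61e-09, adjusted p = 0.327 with an estimated correlation). Il6 differed by 4.52 (SE 0.64), Socs3 by 4.20 (SE 0.35) and Cebpd by 3.86 (SE 0.36). Proteases had 12 of 20 higher and 1 lower (12 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 6.17e-06, adjusted p = 0.272 with an estimated correlation). Mmp10 differed by 4.58 and Mmp3 by 3.42 (SE 0.42). ERK output had 11 of 27 higher (16 adjusted over the list alone, median 1.05, with 1.42 in WA, -0.01 in WB and 1.55 in WC, camera adjusted p = 6.11e-06, adjusted p = 0.563 with an estimated correlation). The growth factor gene Ereg differed by 2.98 (SE 0.45) and Dusp6 by 2.39. Interferon response had 7 of 19 higher (9 adjusted over the list alone, median 1.30, camera adjusted p = 7.45e-06, adjusted p = 0.563 with an estimated correlation). Ifit3 differed by 3.29 (SE 0.76, adjusted p = 0.0176, 3.04 in WA, 0.91 in WB and 5.91 in WC) and Usp18 by 3.01 (SE 0.64). Glycolysis had 10 of 17 higher (10 adjusted over the list alone, median 0.66, camera adjusted p = 0.000224, adjusted p = 0.364 with an estimated correlation). Slc16a3 differed by 3.61 (SE 0.18) and Hk1 by 0.90 (SE 0.07).

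Integrins and adhesion receptors had 10 of 24 higher with v-src than with c-myc (10 adjusted over the list alone, median 0.26, camera adjusted p = 0.00124, adjusted p = 0.331 with an estimated correlation). The laminin receptor chain Itga6 differed by 2.56 (SE 0.47). Matrix genes had 8 of 34 higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.311). Ecm1 differed by 2.76 (SE 0.34). Contractile genes had 3 of 26 lower (3 adjusted over the list alone, median -0.37, camera adjusted p = 0.0426, adjusted p = 0.780 with an estimated correlation). Srf differed by -1.10 (SE 0.18). The call of this list was lost after quantile normalization. Stress response genes had 9 of 28 higher and 4 lower (10 and 4 adjusted over the list alone, median 0.20, camera adjusted p = 0.00382, adjusted p = 0.618 with an estimated correlation). The chaperone gene Dnajb9 differed by 1.70 (SE 0.12) and Vldlr by 2.13 (SE 0.24). Of 24 p53 targets 3 were higher and 4 lower (3 and 4 adjusted over the list alone, median -0.17, mean 0.04, camera adjusted p = 0.719). Cdkn1a differed by 1.94 and Sesn1 by -1.16. Fibroblast markers had 3 of 16 higher and 2 lower (3 and 2 adjusted over the list alone, median -0.05, mean 0.42, camera adjusted p = 0.675). Pdgfra differed by 3.38 (SE 0.39). Pdgfrb was 1 of the 2 lower (-0.72), a call lost without WB c-myc replicate 2, WC c-myc replicate 1, WB v-src replicate 2 or both arrays apart (adjusted p = 0.0512 to 0.0694). Hox genes had 3 of 20 higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.354). Without WC c-myc replicate 2, Hoxb9 (adjusted p = 0.0523), Hoxd8 (0.0509) and Hoxc6 (0.195) lost their calls. Hoxc6 also lost it without WA empty replicate 3, WC empty replicate 3, WA c-myc replicate 3, WB v-src replicate 2 or both arrays apart (adjusted p = 0.0504 to 0.0920), and Hoxb9 without WC v-src replicate 1 (adjusted p = 0.0522). Of the cholesterol synthesis genes, 1 of 17 was lower (Mvk -0.71, a call lost without both arrays apart at adjusted p = 0.0599, 0 adjusted over the list alone, 5 at unadjusted p under 0.05 in limma, camera adjusted p = 0.182, fry adjusted p = 0.512).

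In limma, v-src against c-myc called 3325 genes, 1548 higher and 1777 lower, with 4949 at unadjusted p under 0.05. At least 2-fold were 574 higher and 159 lower. The count was 1670 without WA, 1914 without WB and 1226 without WC, and 6102 with all arrays as separate values. Over the 81 list tests, camera with the preset correlation called 43 and fry 28. With a correlation estimated on the 9 averages it called 0, with 10 at unadjusted p under 0.05. Run on all 26 arrays with a correlation estimated there, it called 16. That run also takes the spread from the arrays, which may be technical, so it counts arrays of 1 line as separate evidence. Its adjusted p was 0.04998 for ribosome biogenesis, mitochondrial ribosome and fibroblast markers with c-myc. It was also 0.04998 for interferon response with v-src and for nucleotide synthesis with v-src against c-myc. Those 16 were, for c-myc, ribosome biogenesis, mitochondrial ribosome, matrix, integrins, proteases, cytokines and fibroblast markers; for v-src, glycolysis, contractile genes, cytokines and interferon response; and for v-src against c-myc, nucleotide synthesis, integrins, proteases, cytokines and interferon response.

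**Figure D3:**
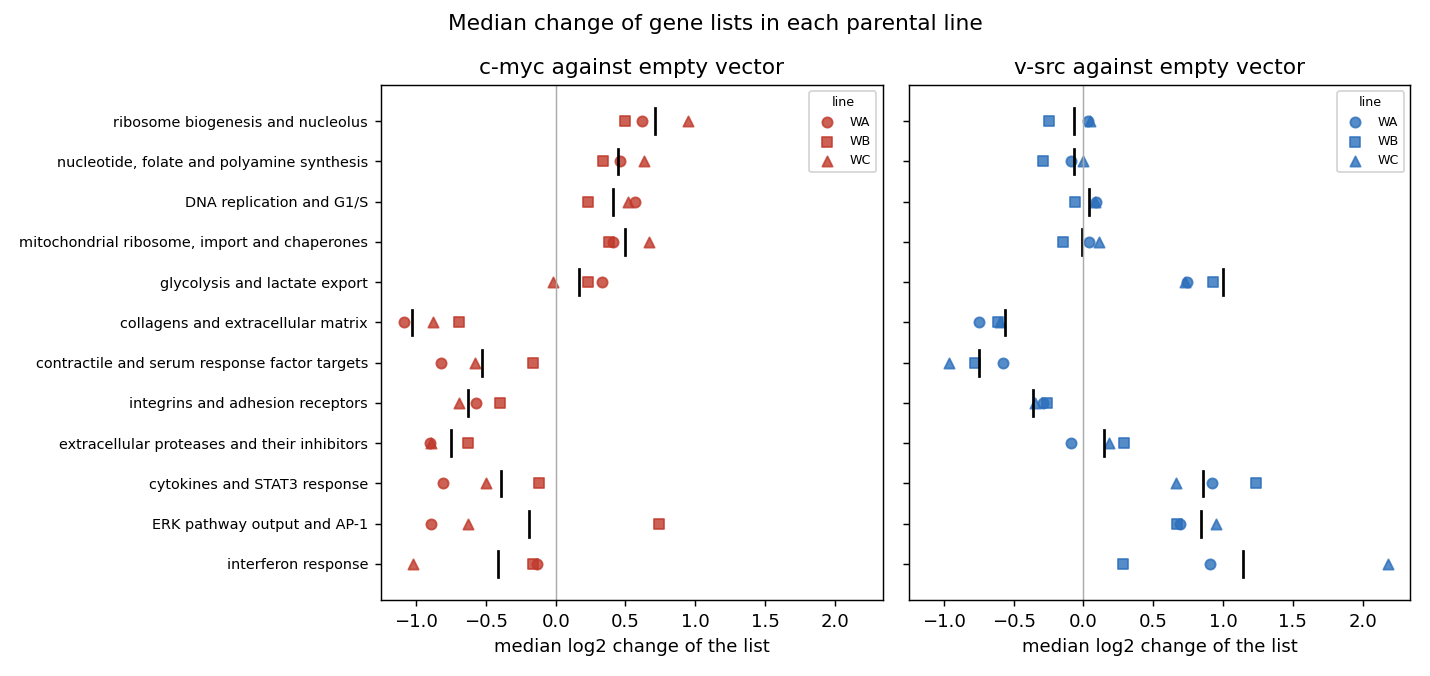
Median log2 change of 12 gene lists with c-myc and with v-src against the empty vector. Markers are the medians in the 3 lines, and the black bar is the median over the list's members of their change over the lines.

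Many of the same genes were lower with either oncogene than with the empty vector. Higher in both comparisons were 159 genes, among them Dyrk3 (2.03 with c-myc and 2.34 with v-src), Aldh2 (1.23 and 1.72), Ak4 (1.23 and 1.69) and Slc16a1 (1.34 and 1.20). Lower in both were 380, among them Smoc2 (-3.15 and -4.85), Cemip (-2.70 and -2.37), Fam20a (-2.35 and -2.58) and Vamp5 (-2.16 and -2.14). Down with c-myc and up with v-src were 80 genes, among them Dkk2 (-2.65 and 1.73), Cebpd (-1.75 and 2.11), Csgalnact1 (-1.52 and 2.12) and the interleukin 4 receptor gene Il4ra (-1.38 and 1.63). Up with c-myc and down with v-src were 25, among them Aven (0.55 and -0.68) and the mitochondrial peroxidase gene Prdx3 (0.51 and -0.54). Both comparisons share the empty-vector arrays. Independent lists of these sizes would share 86.8 genes up, 86.2 down, 88.7 up and down and 84.4 down and up. With the empty-vector arrays split between the comparisons, 73 to 90 genes were higher in both, 270 to 314 lower in both, 4 to 31 up and down and 45 to 71 down and up. The split arrays are of the same line and vector. A deviation common to a line's empty-vector arrays therefore stays in both comparisons, and the splits cannot exclude it as a source of overlap. The fold changes correlated across genes with r = 0.305, against 0.497 in simulations of unchanged groups, where the shared arrays alone act, and 0.217 to 0.279 in the splits. Their covariance was 0.071, against 0.025 simulated and 0.055 to 0.067 in the splits.

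Within single lines, c-myc changed 4889 genes in WA (2478 higher and 2411 lower), 3511 in WB (1626 and 1885) and 4837 in WC (2415 and 2422) in limma, where p-values measure the spread between arrays of 1 group. In all 3 lines 873 genes were called higher and 984 lower, and 281 were called in opposite directions in different lines. For v-src the counts were 3560 in WA (1722 and 1838), 3320 in WB (1558 and 1762) and 3765 in WC (1794 and 1971), with 613 higher in all 3 lines, 733 lower and 202 in opposite directions. The WB count was 2040 without WB v-src replicate 2, which left 1 array of that group.

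The c-myc effect differed between lines for 2105 genes and the v-src effect for 1752 (limma F test, n = 26 arrays, 3867 and 3471 at unadjusted p under 0.05). Egr3, an immediate early transcription factor gene, rose with c-myc in WB alone (-0.89 in WA, 3.28 in WB and -0.72 in WC, adjusted p = 3.44e-09), where its signal went from 140 ± 12.7 (SD, n = 3 arrays) to 1566 ± 61.0. Errfi1, a feedback inhibitor of the EGF receptor, changed by -1.18, 1.67 and -0.33 in the same order (adjusted p = 3.73e-10), Ch25h by -1.58, 1.24 and 0.32 (adjusted p = 1.40e-09), Snai1 by -0.69, 1.09 and -0.56 (adjusted p = 3.33e-09) and Rasa1 by -1.43, 0.14 and -0.36 (adjusted p = 3.33e-09). With v-src, Fhl1 changed by -1.15, -3.82 and -2.92 (adjusted p = 4.11e-10), Cdc42ep3 by -0.83, -0.21 and -3.03 (adjusted p = 1.97e-09), Serpinb2 by 7.25, 2.64 and 6.23, Grb14 by 1.03, 2.48 and -1.08 and Cxxc5 by -1.51, 0.70 and 0.11 (adjusted p = 5.77e-09 for each of these 3). Mouse Myc differed with c-myc (adjusted p = 9.94e-08), and Il33 did not differ with v-src (adjusted p = 0.428).

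With the empty vector, Hoxc8, a homeobox gene of the trunk, had a signal of 6053 ± 363 (SD, n = 3 arrays) in WB and 21.9 in WA (log2 -7.13 for WA against WB, SE 0.26, adjusted p = 6.74e-16). Cyba, a subunit of the NADPH oxidase, had 1619 ± 395 in WA and 3643 ± 244 in WC but 6.29 in WB (-6.97 for WB against WC, SE 0.13, adjusted p = 4.66e-22). Xist, expressed from the inactive X chromosome, had 5268 ± 201 in WA, 235 ± 21.5 in WB and 5957 ± 521 in WC, and the Y chromosome gene Kdm5d 30.8, 309 ± 18.2 and 60.2. Uty, also on the Y chromosome, was lower in WA than in WB (-1.97, SE 0.26, adjusted p = 3.60e-06) and higher in WB than in WC (1.89, SE 0.26, adjusted p = 4.86e-06). WA had more Slc38a4 (5.39) and Tnmd (4.88) and less Dlk1 (-5.24) and Serpinb6b (-5.13) than WB. It had more Tnmd (6.58), Srpx2 (5.51) and Pdzrn3 (5.11) and less Il1rn (-6.70, SE 0.41, adjusted p = 9.49e-12), Penk (-5.85) and Sod3 (-5.81) than WC. WB had more Pdzrn3 (6.73), Dusp4 (6.35) and Hoxc8 (6.30) and less Stmn2 (-7.11) and Il1rn (-6.55) than WC. Cdkn1a was lower in WA (-1.83) and in WB (-2.13, adjusted p = 2.74e-07) than in WC.

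Interferon response genes were lower in WA than in WC, 14 of 19 (15 adjusted over the list alone, median -1.40), and lower in WB than in WC, 15 of 19 (16 adjusted over the list alone, median -1.30). Ribosome biogenesis genes were higher than in WC in WA, 26 of 33 (26 adjusted over the list alone, median 0.44), and in WB, 24 of 33 (25 adjusted over the list alone, median 0.52). DNA replication genes were higher in WB than in WC, 19 of 30 (23 adjusted over the list alone, median 0.42), and 16 of 30 were lower and 1 higher in WA than in WB (16 and 1 adjusted over the list alone). Of 20 Hox genes 9 were lower in WA than in WB (9 lower and 1 higher adjusted over the list alone), and 11 were higher and 4 lower in WB than in WC (11 and 5 adjusted over the list alone). In limma 3395 genes differed between WA and WB (1657 higher and 1738 lower), 3881 between WA and WC (1917 and 1964) and 4232 between WB and WC (2148 and 2084).

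Of 8 macrophage and blood markers none was called with c-myc (0 of 8 in limma and 0 at unadjusted p under 0.05, camera adjusted p = 0.907, fry adjusted p = 0.295; median 0.13, mean -0.01), and 2 rose with v-src, Cd53 and Cd14 (2 adjusted over the list alone, median 0.32, camera adjusted p = 0.00660, adjusted p = 0.331 with an estimated correlation). Cd53 had signals of 121 in WA, 180.1 in WB and 72.2 in WC with the empty vector and 1221, 3504 and 1679 with v-src, and Cd14 rose by 1.69 (SE 0.31, adjusted p = 0.0124). Both were higher than with c-myc (2 adjusted over the list alone, camera adjusted p = 0.0359, adjusted p = 0.364 with an estimated correlation). The call of this list was lost after quantile normalization and with no filter. Of 8 endothelial markers Egfl7 rose with c-myc (0.70, a call lost without WC empty replicate 2 at adjusted p = 0.0539, without WC v-src replicate 3 at 0.0559, and in other settings up to 0.103, 0 adjusted over the list alone, 1 at unadjusted p under 0.05 in limma, camera adjusted p = 0.808, fry adjusted p = 0.555) and none was called over the lines with v-src (0 at unadjusted p under 0.05 in limma, camera adjusted p = 0.986, fry adjusted p = 0.877). Within WC Egfl7 fell with v-src by 0.42 (SE 0.12, adjusted p = 0.00879). Of 8 epithelial markers none was called with c-myc (camera adjusted p = 0.736) or v-src (camera adjusted p = 0.415). Of 9 skeletal muscle markers none was called with c-myc (camera adjusted p = 0.496), and with v-src Chrna1 rose (1.23, call lost without WC c-myc replicate 1 at adjusted p = 0.0571 and without both arrays apart at 0.0742) and Tnnt2 fell (-1.62, call lost without WC empty replicate 3 at adjusted p = 0.0566, 1 and 1 adjusted over the list alone, camera adjusted p = 0.832). Of 8 neural and glial markers Map2 fell with c-myc (-1.26, SE 0.19, 2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.496) and with v-src (2 rose and 1 fell adjusted over the list alone, median 0.29, mean -0.06, camera adjusted p = 0.693). Of 9 adipocyte and chondrocyte markers Col11a1 fell with c-myc (-1.90, 1 adjusted over the list alone, camera adjusted p = 0.719), and with v-src Fabp4 rose and Col11a1 and Col2a1 fell (2.24 and -2.56 for the first 2, 2 and 2 adjusted over the list alone, camera adjusted p = 0.415). Over the 3 lines none of the 3 sex chromosome genes tested was called with c-myc (camera adjusted p = 0.305) or v-src (camera adjusted p = 0.504). Within WB alone Xist rose with c-myc by 0.55 (SE 0.10, adjusted p = 0.000172) on the probe set kept, and its c-myc effect differed between lines (adjusted p = 0.0339). The mean signals of its 2 other probe sets in WB went from 15.9 to 17.2 and from 13.5 to 18.4.

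Between v-src and c-myc, 1 of 8 endothelial markers was lower (0 adjusted over the list alone, camera adjusted p = 0.815), 0 of 8 epithelial markers were called in limma (2 at unadjusted p under 0.05, camera adjusted p = 0.719, fry adjusted p = 0.616), 1 of 9 skeletal muscle markers was higher, Chrna1, and 1 lower (the first call lost without WC c-myc replicate 1 at adjusted p = 0.0516 and without both arrays apart at 0.0599, camera adjusted p = 0.657), 2 of 8 neural markers were higher and 1 lower (Tubb3 1.30 and Map2 -1.65, camera adjusted p = 0.624), 1 of 9 adipocyte and chondrocyte markers was higher and 1 lower (Fabp4 2.61 and Lpl -1.23, the latter lost with the mean of probe sets, camera adjusted p = 0.565) and 0 of 3 sex chromosome genes were called (0 at unadjusted p under 0.05, camera adjusted p = 0.719). The log2 ratio of the 3' to the 5' control probe sets of Gapdh was -0.33 ± 0.02 (SD, n = 3 lines) with the empty vector, -0.32 ± 0.03 with c-myc and -0.27 ± 0.02 with v-src, and that of Actb 0.19 ± 0.01, 0.21 ± 0.04 and 0.21 ± 0.01.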

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

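The tests of a weaker c-myc response and of growth state for the ERK genes, of a low resting level for the interferon genes and of macrophage or blood cells were chosen only after the results were seen.

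ERK output genes moved in opposite directions with c-myc, up in WB and down in WA and WC, and a test of the difference between lines picked this out (WB against WA, median difference 1.63, adjusted p = 0.009701 with an estimated correlation; WC against WB, -1.10, adjusted p = 0.0197). In WB, 18 of 27 members such as Egr3 were called higher and 4 lower. In WA 1 was called higher and 22 lower, and in WC 1 higher and 17 lower. A c-myc response that was only weaker in WB would keep the direction of WA and WC. The direction in WB is the pattern itself, so this count is not an independent test of that explanation. No single array carries it: the median in WB minus the mean of WA and WC was 1.39 at its lowest, without WC empty replicate 3. Growth state of the cultures at harvest cannot be told apart from an effect of the line, because all 3 of 3 WB c-myc arrays lay above every WB empty-vector array, as both would give. An effect of the parental line is the biological explanation that stays open, untested.

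Interferon response genes rose with v-src in WC more than in the other lines (WC against WB, median difference 2.02, adjusted p = 0.0197 with an estimated correlation; WC against WA, 1.36, adjusted p = 0.04593), with 18 of 19 members called higher in WC, 11 in WA and 2 in WB. The difference of 1.59 between WC and the mean of WA and WB was 1.34 at its lowest, without WC empty replicate 3, so no single array carries it. A low resting level in WC is argued against by the levels: the list's mean log2 signal was 8.68 in WC with the empty vector against 7.40 in WA and 7.31 in WB, and with v-src WC lay 2.96 above the mean of the others. Macrophage or blood cells in the WC v-src arrays stay open. The 14 markers on the array, 6 of them below the filter, had a median change of 0.26 in WC with an SD of 1.32. Cd53 (4.17), Cd14 (2.46) and Mpeg1 (1.62, below the filter) rose there. Laptm5 (-0.52) fell there, as did Tyrobp (-0.35), Itgam (-0.52) and Hba-a1 (-0.53), which lie below the filter. The other markers rose there by 0.06 to 0.44. Cd53 rose about as much in WB (4.13), where 2 of 19 interferon members were called higher. A stronger interferon response of WC to v-src stays open beside macrophage or blood cells, untested.

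Cd53 and Cd14, leukocyte genes, rose with v-src, from a signal of 125 to 1963 and from 314 to 1400. The other 12 macrophage and blood markers, 6 of them below the filter, had median changes of 0.20 in WA, 0.06 in WB and 0.21 in WC (SD 0.40, 0.40 and 0.60). In WA, WB and WC, Fcer1g changed by 0.23, 0.95 and 0.35 and Laptm5 by 1.05, -0.11 and -0.52. Lyz2 changed by 0.19, -0.22 and 0.25 in the same order. Cd68, Adgre1 and Csf1r rose in each line, by 0.05 to 0.48. Below the filter, Mpeg1 changed by 0.54, 0.46 and 1.62 and Ctss by 0.78, -0.00 and 0.06. Also below it, Ptprc changed by -0.07, -0.17 and 0.38 and Tyrobp by -0.38, 0.68 and -0.35. Itgam (-0.13, -0.03 and -0.52) and Hba-a1 (0.17, -0.34 and -0.53) lay below it too. The markers went both ways, so macrophage or blood cells in the v-src arrays stay open. Hybridization of 1 probe set to another transcript stays open: the lowest change among probe sets past the filter was 1.69, but Cd14 has 1 probe set, and the second one of Cd53, below the filter, changed by 0.80. The biological explanation, induction in the fibroblasts, was not tested.

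The difference of the c-myc effect between lines held for 2105 genes, among them 42 of the 99 genes named for c-myc; the smallest p were those of Errfi1 (adjusted p = 3.73e-10), Ch25h (1.40e-09), Snai1 (3.33e-09), Rasa1 (3.33e-09) and Egr3 (3.44e-09). The v-src effect differed for 1752 genes, among them 46 of the 90 named for v-src, led by Fhl1 (adjusted p = 4.11e-10), Cdc42ep3 (1.97e-09), Serpinb2 (5.77e-09), Grb14 (5.77e-09) and Cxxc5 (5.77e-09). When the vectors were shuffled among the arrays within lines, 5 of 100 arrangements, the real one included, gave as many genes for c-myc (highest other 5238) and 4 of 100 for v-src (highest other 4334). These shares do not decide whether chance can be excluded and do not set the 2 results apart, because the draws behind them leave the vectors of some line together. Arrangements that call at least as many genes as the real one point to a structure of the samples. All 4 such draws for c-myc and all 3 for v-src kept or exchanged the vectors of a line as a whole. Among the draws that did neither in any line the highest count was 1 for c-myc and 2 for v-src.

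Cytokine and STAT3 response genes differed between lines with c-myc (WB against WA, median difference 0.58, adjusted p = 0.009701; WC against WB, -0.39, adjusted p = 0.0197) and with v-src (WC against WB, -0.68, adjusted p = 0.009701; WB against WA, 0.40, adjusted p = 0.0197). Cholesterol synthesis genes differed with c-myc (WC against WA, -0.94, adjusted p = 0.02007). Of 162 such tests, which take the spread from the arrays, 65 were called with the preset correlation and 9 with an estimated one.

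Of the probe sets without a gene name, which no comparison above uses, 3277 passed the filter and 129 were called with c-myc (75 higher and 54 lower) and 173 with v-src (109 higher and 64 lower) in limma. The largest changes with v-src were 5.73 (SE 0.40, n = 3 lines) and -2.98 (SE 0.67), and with c-myc 1.53 (SE 0.15) and -2.22 (SE 0.26).

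The other comparisons of 3 against 3 allow 10 splits, too few for a share under 0.05; the real split, 1 of 10 in each, is given with the highest other count. Over the lines these were 2576 and 0 for c-myc, 1749 and 1 for v-src and 3325 and 0 for v-src against c-myc. Within lines they were 4889 and 1 (c-myc in WA), 3511 and 0 (c-myc in WB), 4837 and 753 (c-myc in WC), 3560 and 3 (v-src in WA) and 3765 and 1 (v-src in WC). Between lines they were 3395 and 0 (WA and WB), 3881 and 79 (WA and WC) and 4232 and 1 (WB and WC).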

How the results depend on the processing

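The correlation estimated on all arrays and the joint removal of 2 arrays were tests chosen only after the results were seen. The direction and side of the threshold of named genes held in 13022 of 13590 values over the alternatives, 522 lost the call, 45 gained it and 1 reversed. Many of these values come from leaving out single arrays. Leaving out a line lost far more: 108 calls without WA, 91 without WB and 105 without WC, where 186, 202 and 189 values held. The reversal was that of Mycn, not called at -0.03 for v-src against c-myc and called at 0.15 after quantile normalization (the cause was not tested). Of 405 list values 324 held, 78 lost the call, 2 gained it and 1 reversed: cytosolic ribosomal proteins with v-src went from -0.12 to 0.03 after quantile normalization (the cause was not tested). All 350 values of the genes named for differing between lines held. Those genes were named for the smallest p in the same data, and none of these settings left out a line. That they held therefore does not bear on the other calls of a difference between lines. Of the 43 list calls, 0 were made with an estimated correlation on the 9 averages and 16 with camera run on all arrays. The latter run counts arrays of 1 line as separate evidence. With all arrays as separate values the counts were 5801 for c-myc, 4953 for v-src and 6102 for v-src against c-myc, with 2070 shared by both vectors (539 in the report's analysis); with line and vector as a random block they were 4194 and 3321 with 1221 shared. Both count arrays of 1 line as separate evidence. Leaving out lines or arrays gave 414 to 2598 for c-myc, 517 to 1821 for v-src, 1226 to 3394 for v-src against c-myc and 104 to 567 shared; the low ends came from leaving out a line, which leaves 2. For v-src in WB the range was 2040 to 3550, lowest without WB v-src replicate 2, where the lone array is assumed to vary like the other groups. Without both arrays apart from their group, WA empty replicate 3 and WC c-myc replicate 1, c-myc called 2468 and v-src 1436. Of the calls after quantile normalization, 2482 of 2531 for c-myc and 1609 of 1708 for v-src were shared. Signals near background, which spread most on the log scale, and 3 lines limit what small changes can be called.

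With the replicate number as a block the counts were 5457, 4541 and 5781, with 1861 shared. The numbers do not pair the arrays: the deviations of 25 pairs with the same number correlated across genes with r from -0.14 to 0.21 (median -0.01), and 8 of 26 arrays correlated best with their own number.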

Other observations

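The test of a smaller c-myc response in WB was chosen only after the result was seen; the hypoxia list was composed after the glycolysis result and before its own test.

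Genes that cells induce when oxygen is low rose with v-src beyond glycolysis. Of 32 hypoxia-inducible genes outside the glycolysis list, 16 rose and 1, Pfkfb4, fell. The median was 0.68 (0.64 in WA, 0.78 in WB and 0.69 in WC). Camera gave an unadjusted p = 3.45e-11, and an unadjusted p = 0.00708 with a correlation estimated on the averages. This list was tested by itself, so its p-values are not on the scale of the adjusted ones of the 27 lists. There, a correlation estimated on the averages gave 10 unadjusted p under 0.05 and 0 calls. Run on all arrays with a correlation estimated there, camera gave an unadjusted p = 0.000498, which counts arrays of 1 line as separate evidence. The mitophagy receptor gene Bnip3 rose by 2.99 (SE 0.34, n = 3 lines), the oxygen sensor gene Egln3 by 2.44 (SE 0.36), Ndrg1 by 1.90 (SE 0.14) and Mxi1 by 1.51 (SE 0.12). With c-myc the median of the same list was -0.10, with 2 members up and 7 down in limma, and camera did not call the list. The median of 0.68 suggests a wider hypoxia-type response with v-src; oxygen and HIF protein were not measured here.

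Sox2, a transcription factor gene of stem and neural cells, was the single gene with a mean signal above 500 in 1 group and below 50 in the 8 others, a search made after its values were seen. Its signal was 1071 ± 59.1 (SD, n = 3 arrays, 1032 to 1139) in WC with v-src and at most 39.4 elsewhere.

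The c-myc response in WB may be smaller over all genes. The spread of effects across genes was 0.418 in WB, 0.540 in WA and 0.493 in WC, a ratio of 0.810 for WB to the mean of the others and 0.840 at the highest without each array in turn. The v-src ratio was 1.024.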
